A study of Mus musculus with 16 samples.

How the data were processed

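RNA sequencing was done on hearts of male and female mice of the C57BL/6 strain, either wild type (WT) or carrying a transgene that overexpresses SUR2A-55 in the heart (TG). SUR2A-55 is a short form of the sulfonylurea receptor SUR2, the regulatory subunit of cardiac ATP-sensitive potassium (KATP) channels, which is encoded by Abcc9. There were 4 hearts in each of the 4 groups of sex and genotype, 16 in all. Per the labels' protocols, total RNA was taken from frozen tissue with an on-column DNA digest, and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and marks strand.

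The authors deposited estimated counts per gene, in whole numbers and not scaled to library size, for 51912 genes. Per the submitters' processing notes, STAR, RSEM, bcl2fastq 2.20.0.422, R 3.6.2 and the mm10 build were used, with no role or order given. RSEM gives expected counts that need not be whole, so the deposited values were read as rounded estimates; the rounding, the annotation release and the strand setting of the counting are not given in the sources used here. RSEM shares reads among genes with similar sequence, so genes with near-identical copies are uncertain, and reads at overlapping genes on opposite strands may not have been told apart. Positions come from GENCODE vM21 on GRCm38, the same assembly as mm10; 51719 of the gene identifiers (99.6%) matched it, as did 15035 of the tested ones.

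Each sample was assigned to its group by the sex and genotype in the labels. Replicates were numbered within a group in accession order, so the numbers pair nothing. The titles carry sample numbers that fall into series 477, 479, 488, 493 and 499. Below, 477 and 479 are called the earlier series and 488, 493 and 499 the later series. They were spread unevenly within each sex, since the earlier series held 3 of 4 female TG, 1 of 4 female WT, 3 of 4 male WT and 1 of 4 male TG hearts. Pooled in this way, the series are balanced over the genotype comparison across both sexes. They are partly mixed with genotype inside each sex and with sex inside each genotype, and aligned with the genotype by sex interaction. The single series are not balanced: 477 held 1 TG female, and 493 and 499 held only WT females (replicates 3 and 4). A term for earlier against later series cannot adjust for differences among the pooled series. What the numbers stand for is not stated. Whether each library is a separate animal is taken from the labels' wording of mouse hearts.

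Total counts ran from 29152118 to 41710689 per library. The 2 most alike libraries of one group differed by a chi-square of 8.01 per degree of freedom over genes with a mean count of at least 20, so no library was treated as a duplicate. Genes were kept by edgeR's filterByExpr on the groups, which left 15060. Counts were scaled by the trimmed mean of M values (TMM), and edgeR 4.0.16 in R 4.3.3 fitted 1 quasi-likelihood model with a mean for each group (glmQLFit with robust estimation, glmQLFTest). The contrasts tested were TG against WT across both sexes, in females and in males, the difference between these genotype effects (interaction), and female against male in WT and in TG. A gene was called at a Benjamini-Hochberg adjusted p (FDR) under 0.05. Standard errors (SE) of log2 fold changes were taken from the quasi-likelihood F. CPM are counts scaled to the TMM-adjusted library size, and error on them is the SD over n = 4.

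Gene lists, 47 in number, were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes followed a rule. For each comparison the 10 called genes with the smallest p in each direction were taken, among genes with a symbol that is not a predicted one and a mean log2 CPM of at least 0. To these were added Abcc9, Kcnj11, Kcnj8 and Abcc8, and up to 4 members with the smallest p of each list described. Where fewer than 5 genes were called, the 5 with the smallest p are given as values. The groups, tests, lists, rule and a set of other settings were fixed before the data were examined. These settings were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no filter, a filter of 1 CPM in 4 samples, only the groups compared, a term for the sample number series, a fold of 2, an FDR of 0.10, leaving Abcc9 and Myh6 out, and leaving out each library. Fits without the 4 libraries in which the atrial marker Myl7 exceeded 5 CPM, with the mitochondrial share as a term, and within the earlier and within the later series, and lists without Abcc9, were added after seeing the data. The earlier series alone holds 1 WT female and 1 TG male, and the later series alone 1 TG female (replicate 4) and 1 WT male, so each fit within a series has groups of 1 heart, which are assumed to vary like the other groups.

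The procedure was tested on simulated counts with the real means, dispersions and library sizes, in which 200 genes were changed. A separate list of genes was also shifted by 0.3 on the log2 scale, to test camera. For TG against WT across both sexes, over 14933 genes, it recovered 20% of genes changed by a fold of 1.25, 70% at 1.5, 94% at 2 and 100% at 4, with 7 calls among 14830 unchanged genes. In females 46% were recovered at a fold of 1.5 and 78% at 2, in males 52% and 86%, and for the interaction 12% and 56%. Each share rests on 50 genes. The simulated genes varied independently of one another, without structure among hearts such as in mitochondrial share, atrial markers or series. The few false calls therefore do not show how many the real data would give. In the data, the 95% confidence interval lay within a fold of 1.5 in either direction for 83.9% of genes in the comparison across both sexes, 68.5% in females, 72.2% in males and 53.6% for the interaction. In females 1 gene had no defined SE and was left out of that share. A floor of 3 counts over the group was used where a group had none; it covers counting error only.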

Results

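The data are estimated read counts from 16 mouse hearts, 4 each of WT females, TG females, WT males and TG males. Total counts averaged 32.7 ± 2.63 M (SD, n = 4) in WT females, 33.1 ± 5.74 in TG females, 35.7 ± 2.94 in WT males and 31.3 ± 3.2 in TG males. Mitochondrially encoded mRNAs took 25.6% ± 0.625 of counts in WT females, 24.4% ± 0.683 in TG females, 27.0% ± 1.85 in WT males and 27.6% ± 1.85 in TG males. Female minus male was -3.27 percentage points in TG (two-sided exact permutation test, p = 0.057, adjusted p = 0.34 over 12 library comparisons), a difference that did not pass. With 4 hearts against 4 the p of this test cannot be very small. It could hardly pass over 12 comparisons, and the shares may still differ. The nuclear mitochondrial copies Gm28437, Gm28661 and Gm10925 took between 8.85% and 11.1% of counts, and reads could be split between them and the mitochondrial genes, so both shares are uncertain.

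Genotype across both sexes asks what the transgene changed in the heart. Abcc9, the gene of the SUR2 subunits, rose in TG hearts by 3.84 on the log2 scale (SE 0.09, FDR = 5.69e-15, edgeR quasi-likelihood test), a fold of 14.3. It averaged 6732 ± 837 CPM in TG and 459 ± 36.5 in WT females, and 6198 ± 529 against 446 ± 74.0 in males (SD, n = 4), and every TG heart lay above every WT heart. The counts cannot tell the transgene's transcript from the native Abcc9 on chromosome 6 (142587862 to 142702315, ENSMUSG00000030249). Fign, which encodes the microtubule-severing protein fidgetin, rose by 0.87 (SE 0.11, FDR = 0.0041), and Kcnh7, a voltage-gated potassium channel gene, fell by 0.93 on the log2 scale (SE 0.13, FDR = 0.010). Both lie on chromosome 2, Fign at 63971507 to 64098038 and Kcnh7 at 62693414 to 63184287. These 3 genes were the calls among 15060, of which 2 were higher and 1 lower. At an unadjusted p under 0.05 there were 878 genes, where chance gives 753. Limma-voom called 4, adding Gca, and DESeq2 9, adding Gca, Ifih1, Grb14, Kcnv2, Cyp26b1 and Gm43146, and without a filter edgeR called 6. Kcnh7 lost its call without 4 libraries that held atrial markers (log2 fold change -0.90, FDR = 0.14). With the earlier and later series of sample numbers fitted apart, where 2 of the 4 groups hold 1 heart, neither was called: Fign had 0.79 (FDR = 0.18) in the earlier and 0.75 (FDR = 1) in the later series, Kcnh7 -1.26 (FDR = 0.60) and -0.65 (FDR = 1), while with the series as a term both were (FDR = 0.0073 and 0.014).

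**Figure D1:**
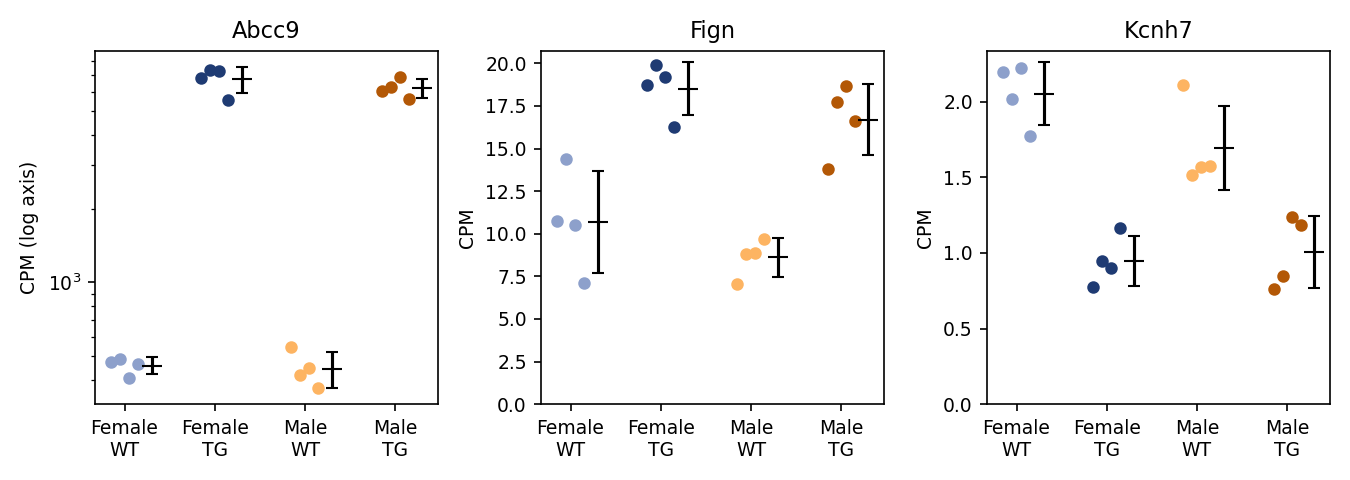
CPM of Abcc9 (log axis), Fign and Kcnh7 in each of 16 hearts, by group; points are hearts, and the bar beside them is the mean ± SD (n = 4). Within each sex every TG heart lies above every WT heart for Abcc9 and Fign and below every WT heart for Kcnh7.

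**Figure D2:**
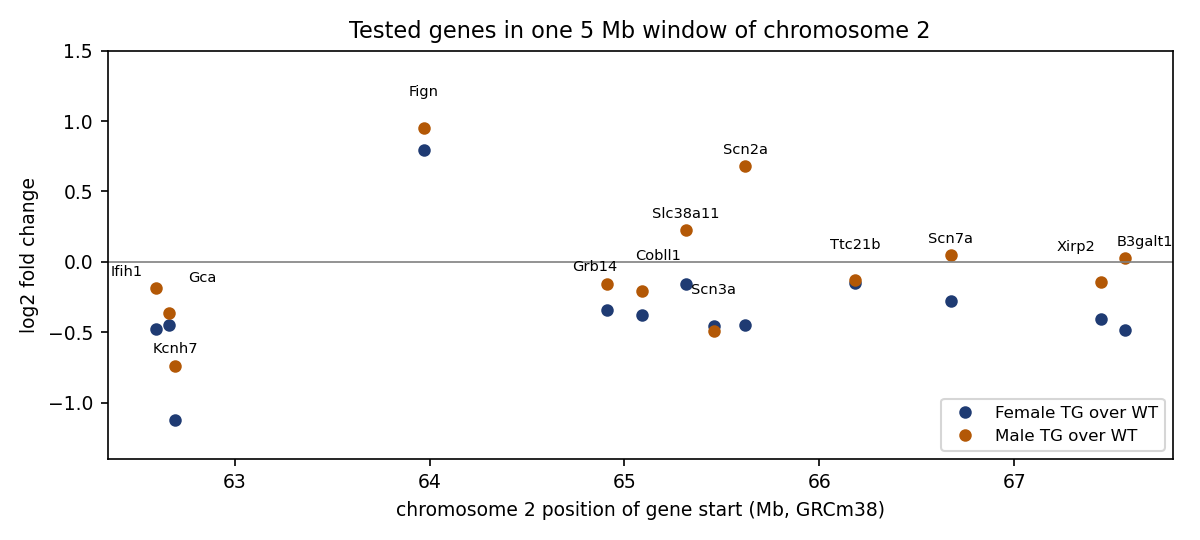
Log2 fold change of TG over WT in females and in males for the 13 tested genes that start in one 5 Mb window of chromosome 2, against the start of the gene in Mb (GRCm38). Fign lies above 0 and Ifih1, Gca, Kcnh7, Grb14, Cobll1 and Scn3a below 0 in both sexes.

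The other KATP genes did not pass. Kcnj11, the pore-forming Kir6.2 subunit, had a log2 fold change of 0.19 (SE 0.08, FDR = 0.80), Abcc8, the gene of SUR1, 0.18 (SE 0.09, FDR = 0.80), and Kcnj8, the Kir6.1 subunit, 0.06 (SE 0.06, FDR = 0.85). Gca and Gm43146, next by p, had -0.41 (FDR = 0.088) and -0.73 (FDR = 0.0965). The 5 tested KATP members as a list were called (camera adjusted p = 7.34e-64, adjusted p = 4.22e-07 with an estimated correlation). Without Abcc9 the remaining members had an adjusted p of 0.0693 where it was left out of the lists, which did not pass, and of 0.0486 where Abcc9 and Myh6 were left out of the data, which did. The smooth muscle and pericyte list, which also holds Abcc9, was called at the preset correlation (adjusted p = 5.49e-14) and not with an estimated one (adjusted p = 0.066); without Abcc9 its adjusted p was 0.746.

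Camera called 12 of 47 lists at its preset correlation, 8 up and 4 down; with an estimated correlation 1 was called, and fry called 1. Of 26 cell cycle genes 24 were lower in TG, with a median log2 fold change of -0.57 (list adjusted p = 8.76e-11, adjusted p = 0.74 with an estimated correlation). Of these genes 0 passed alone, including over the list alone, and Mki67 (-0.79, SE 0.24), Top2a (-0.84, SE 0.28) and Aurkb (-0.86, SE 0.30) had the smallest p. In males their mean log2 CPM followed the sample number series rather than genotype (1.23 to 1.52 in the earlier, 0.65 to 0.82 in the later). All 16 tested MHC class I and II genes were higher, with a median of 0.30 (adjusted p = 2.28e-07, adjusted p = 0.74 with an estimated correlation); H2-DMa had 0.50 (SE 0.18) and Cd74 0.34 (SE 0.15). Of 46 ribosomal protein genes 43 were higher, median 0.084 (adjusted p = 1.95e-05), and of 36 Complex I genes 29, median 0.058 (adjusted p = 0.0029). Of 35 extracellular matrix genes 30 were lower, median -0.12 (adjusted p = 0.0015), with Postn at -0.28 (SE 0.09). Without the 4 libraries with atrial markers Postn was called at -0.46 (FDR = 0.0018). The WT and TG females left in that fit share no series, so the Postn call is not clear of series. For the ribosomal protein, Complex I and extracellular matrix lists the adjusted p was 0.74 with an estimated correlation. The remaining calls, all at adjusted p = 0.74 with an estimated correlation, were Complexes II to IV (adjusted p = 0.019), the circadian clock (adjusted p = 0.024) and erythroid and platelet markers (adjusted p = 0.017), which were up, and heat shock and ER chaperones (adjusted p = 0.021) and fetal and hypertrophy genes (adjusted p = 0.043), which were down. The fetal list had a median of -0.09 and a mean of 0.08, holds the atrial markers Myl4, Mybphl and Nppa, and scored highest in the 4 libraries with atrial markers. Ribosomal proteins turned to down without the 4 libraries with atrial markers (adjusted p = 0.98), MHC genes in the later series (adjusted p = 0.62), and extracellular matrix genes to up in the earlier series (adjusted p = 0.38), though each series has 2 groups of 1 heart. Without female WT replicate 3, 7 lists were called.

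In females Abcc9 rose by 3.88 (SE 0.13, FDR = 1.89e-12, edgeR). It was the only edgeR call of 15060 genes, with 1254 genes at an unadjusted p under 0.05 against 753 by chance, 9 calls by DESeq2 and 2 by limma-voom. The next by p were Kcnh7 (-1.12, SE 0.19, FDR = 0.10), Gm43146 (-1.0, SE 0.19, FDR = 0.255), Ifih1, a sensor of viral RNA (-0.48, SE 0.09, FDR = 0.28), and Fign (0.79, SE 0.16, FDR = 0.31). Kcnj11 had 0.36 (SE 0.11, FDR = 0.59), Abcc8 0.37 (SE 0.12, FDR = 0.59) and Kcnj8 0.12 (SE 0.09, FDR = 0.70). Adjusted over the list alone 3 of the 5 KATP members rose, Abcc9, Kcnj11 and Abcc8, against 1 over all genes. The KATP list was called in females (adjusted p = 5.30e-37, adjusted p = 6.38e-06 with an estimated correlation), and also with Abcc9 left out of the lists (adjusted p = 0.011 at the preset correlation). The KATP list did not pass in the test of the difference between the sexes (5 of 5 higher in females, adjusted p = 0.0773). Without female WT replicate 2 or TG female replicate 1 edgeR called 2 genes, and with the 8 female libraries alone 10, all higher. The 9 DESeq2 calls were 2 higher and 7 lower. Without the 4 libraries with atrial markers edgeR called 8, 1 higher and 7 lower, with Postn, which encodes the matrix protein periostin, at -0.94 and FDR = 3.54e-05. The WT females left are replicates 3 and 4, which share no series with the TG females left. The 7 lower calls, Postn among them, are therefore not clear of series. Camera called 8 lists, of which cell cycle (24 of 26 lower, adjusted p = 8.83e-08), MHC class I and II (16 of 16 higher, adjusted p = 0.0014) and mitochondrially encoded mRNAs (13 of 13 lower, adjusted p = 0.0031) had an adjusted p of 0.96 with an estimated correlation. So had fetal and hypertrophy genes (14 of 18 lower, adjusted p = 0.0045), ribosomal proteins (33 of 46 higher, adjusted p = 0.012) and X-linked escape genes (5 of 5 lower, adjusted p = 0.034), the last with TG female replicate 4 lacking Xist. The fetal list scored highest in the 4 libraries with atrial markers, of which 2 are WT and 1 is TG among females, and was also lower without them (adjusted p = 8.58e-05). That fit cannot tell genotype from series among females. Smooth muscle and pericyte markers, which hold Abcc9, had an adjusted p of 7.59e-10 and an adjusted p of 0.20 with an estimated correlation. Ribosomal proteins turned to down without the libraries with atrial markers (adjusted p = 0.72), and without female WT replicate 4, 13 lists were called.

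In males Abcc9 rose by 3.80 (SE 0.13, FDR = 2.52e-12, edgeR), again the only call; 496 genes had an unadjusted p under 0.05, DESeq2 and limma-voom each called 2, and both added Fign. Without female WT replicate 2 or 4 edgeR called 2, adding Fign. In the edgeR test Fign had 0.95 (SE 0.16, FDR = 0.12) and Kcnh7 -0.74 (SE 0.19, FDR = 1). Rgs4, a regulator of G protein signalling, had -0.29 (SE 0.07) and 4930525G20Rik 1.28 (SE 0.33), both at FDR = 1. Kcnj11 had 0.01 (SE 0.11), Kcnj8 0.00 (SE 0.09) and Abcc8 -0.01 (SE 0.12), all at FDR = 1. Camera called 19 lists at the preset correlation and 1 with an estimated correlation. Heat shock and ER chaperones were lower in 23 of 27 (adjusted p = 3.03e-04, adjusted p = 0.51 with an estimated correlation), and PPAR targets, genes of lipid use, in 17 of 22 (adjusted p = 0.0021, adjusted p = 0.68 with an estimated correlation). Cell cycle genes were lower in 22 of 26 (adjusted p = 1.80e-04), MHC class I and II genes higher in 16 of 16 (adjusted p = 5.74e-05) and mitochondrially encoded mRNAs higher in 13 of 13 (adjusted p = 0.0085), each at adjusted p = 0.68 with an estimated correlation. The cell cycle genes followed the sample number series rather than genotype. Their mean log2 CPM was 1.23 to 1.52 in male hearts of the earlier series, with TG replicate 1 at 1.31. In the later series it was 0.65 to 0.82, with WT replicate 4 at 0.65. Also called were Complex I, Complexes II to IV, ATP synthase, circadian clock, interferon response, inflammation, ribosomal protein, conduction system and skeletal muscle genes, up, and extracellular matrix, kinase pathway and endothelial genes, down, at adjusted p of 0.68 or more with an estimated correlation. Male scores of the clock (4.28 to 4.48 in the earlier, 4.66 to 4.80 in the later series) also split by series. So did PPAR targets (6.87 to 7.21 and 6.34 to 6.79) and the kinase pathway (5.37 to 5.44 and 5.25 to 5.33). For the clock, TG replicate 1 had 4.34 and WT replicate 4 had 4.75. These calls are not clear of the series. The smooth muscle and pericyte list was called up (adjusted p = 1.06e-05, adjusted p = 0.51 with an estimated correlation) with a median of -0.05 and a mean of 0.18, and turned to down without Abcc9 (adjusted p = 0.441). The KATP list (adjusted p = 4.10e-34, adjusted p = 1.13e-05 with an estimated correlation) did so too (adjusted p = 0.997). PPAR targets were up in the earlier series alone (adjusted p = 7.64e-06), which sets 1 TG male against 3 WT males and so shows no more than that heart's difference. Without male WT replicate 1 or male TG replicate 4, 9 lists were called. Conduction system markers lost their call without the libraries with atrial markers (adjusted p = 0.852). Interferon response genes turned to down without male TG replicate 4 (adjusted p = 0.751), and ribosomal proteins with a term for the series (adjusted p = 0.568).

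Whether genotype acted differently in the sexes was tested by the interaction. No gene was called by edgeR, DESeq2 or limma-voom (0 each); 712 genes had an unadjusted p under 0.05. Without the 4 libraries with atrial markers edgeR called 1, Postn (-0.96, FDR = 0.0017). The WT and TG females left in that fit share no series, so the Postn call is not clear of series. The genes with the smallest p were Nnt (0.80, SE 0.19), Nr1h4 (-1.70, SE 0.42), Lsr (1.35, SE 0.35), Gm15816 (0.67, SE 0.17) and Lbhd1 (-1.18, SE 0.31), each at FDR = 0.90. For Abcc9 the difference was 0.08 (SE 0.16, FDR = 0.96). Camera called 6 lists, all at adjusted p = 0.82 with an estimated correlation. Mitochondrially encoded mRNAs were lower in females relative to males in 13 of 13 (adjusted p = 3.27e-05), interferon response genes in 26 of 30 (adjusted p = 0.012), conduction system markers in 9 of 9 and fetal and hypertrophy genes in 15 of 18 (adjusted p = 0.014 and 0.033). Both lists scored highest in the 4 libraries with atrial markers (2 female WT, 1 female TG and 1 male TG), and atrial markers had a mean difference of -1.63 (adjusted p = 0.127). Without these libraries the conduction list lost its call (adjusted p = 0.702) and the fetal list kept it (adjusted p = 0.0495). Fatty acid oxidation genes were higher in 24 of 30 and PPAR targets in 19 of 22 (adjusted p = 0.014 for both). The series are aligned with this contrast: with a term for them fatty acid oxidation genes lost their call (adjusted p = 0.902) and PPAR targets turned to down (adjusted p = 0.490). Within either series 2 of the 4 groups hold 1 heart, so the direction within a series is not settled. Left-out libraries moved the 6 lists to 1 (male WT replicate 1 or male TG replicate 4), to 3 (female WT replicate 3), to 10 (female WT replicate 2, TG female replicate 1 or male TG replicate 1) and to 11 (male WT replicate 4). Across genes, which are not independent replicates, the female and male genotype effects had a Pearson r of 0.055 and a Spearman rho of 0.052; r was -0.10 with a term for the series. At an unadjusted p under 0.05 in both sexes, 38 genes had the same sign, against 20.1 for independent lists, and 8 opposite signs, against 21.2.

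Female against male WT hearts differed first in sex-linked genes. The Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y were called lower in females; Uty had 0 counts there and was at least 1201-fold lower (3 counts over the group). Of the X-linked genes, Xist, which silences an X chromosome, averaged 333 ± 51.9 CPM in females and 0.32 ± 0.078 in males, and was called (FDR = 0.0067; FDR = 0.054 without male WT replicate 4). Eif2s3x, an X-linked gene that escapes silencing, was higher by 0.70 (SE 0.11, FDR = 0.0067). Among autosomal genes Col14a1, a fibril-associated collagen (1.05, SE 0.14, FDR = 8.26e-04), and Lum, encoding lumican (0.65, SE 0.08, FDR = 7.85e-04), were higher in females. Lower in females were C7, a complement component (-1.98, SE 0.23), Penk, proenkephalin (-1.57, SE 0.20), Hsd11b1, which activates glucocorticoids (-1.29, SE 0.17), and Acsm5 (-1.48, SE 0.17), all at FDR of 8.26e-04 or less. EdgeR called 27 genes, 12 higher and 15 lower in females, 5 on Y, 4 on X and 18 on autosomes. The sample number series is partly mixed with sex here, and with a term for it 21 of these calls were kept. DESeq2 called 69 and limma-voom 65, and scaling by library size alone gave 18 higher and 13 lower. With the mitochondrial share as a term the count was 758, 91 higher and 667 lower, and without male WT replicate 1, which had the highest share of its group (29.8%), it was 44.

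Fatty acid oxidation genes were lower in WT females in 29 of 30 (median -0.18, adjusted p = 4.64e-13, adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone 9 were lower, and 0 over all genes; Slc25a20, the carnitine carrier, had -0.33 (SE 0.08) and Hadh -0.31 (SE 0.08). PPAR targets were lower in 21 of 22 (adjusted p = 1.87e-07, adjusted p = 0.58 with an estimated correlation), and interferon response genes higher in 28 of 30 (adjusted p = 6.67e-07, adjusted p = 0.73 with an estimated correlation). Y-linked genes (adjusted p = 2.55e-11) and X-linked escape genes (adjusted p = 0.0033) held with an estimated correlation. The escape list also holds Xist, with a log2 fold change of 9.99. Camera called 10 lists in all, and 16 without male TG replicate 1. Its remaining calls were the TCA cycle, ketone and branched-chain amino acid use and erythroid and platelet lists, down, MHC class I and II, called down with 8 members higher and 8 lower (median -0.03), and conduction system markers, up in 9 of 9 (adjusted p = 0.0011, and 0.135 without the libraries with atrial markers, 2 of them WT females); for these the adjusted p was 0.58 or more with an estimated correlation.

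In TG hearts the sexes differed in 18 genes by edgeR, 4 higher and 14 lower in females; DESeq2 called 84 and limma-voom 77. Scaled by library size alone, 15 were higher and 11 lower, and without TG female replicate 4, which lacks Xist, 10 were higher and 11 lower. The sample number series is partly mixed with sex here too, and with a term for it 14 of the 18 calls were kept. Armcx4 on the X chromosome (0.89, SE 0.13, FDR = 0.0026), Col14a1 (0.91, SE 0.14, FDR = 0.0055) and Lrrc55 (1.23, SE 0.20, FDR = 0.0079) were higher in females, and C7 (-2.41, SE 0.24), Penk (-1.60, SE 0.20) and Hsd11b1 (-1.38, SE 0.17) lower, at FDR of 4.75e-04 or less. Y-linked genes had 0 counts in TG females, and Ddx3y was at least 3499-fold lower. Xist was called (FDR = 0.017), although TG female replicate 4 had 14 counts of it, and lost its call when any 1 of the 4 male TG libraries was left out (FDR of 0.062 to 0.11). Without male TG replicate 4, 1 of the 4 libraries with atrial markers, 35 genes were called. Mitochondrially encoded mRNAs were lower in females in 13 of 13, with 10 lower adjusted over the list alone and 0 over all genes (median -0.31, adjusted p = 2.98e-10, adjusted p = 0.19 with an estimated correlation); mt-Atp6 had -0.44 (SE 0.10). The mitochondrial share of these libraries differed by -3.27 percentage points. Camera called 13 lists, 8 without TG female replicate 1, and 1, the Y-linked genes, with an estimated correlation. X-linked escape genes, a list that also holds Xist, were up (adjusted p = 2.12e-10, adjusted p = 0.082 with an estimated correlation). The others were macrophage, inflammation, calcium handling, mitochondrial carrier, fatty acid oxidation, TCA cycle, ketone use, erythroid and mesothelial genes, down, and extracellular matrix genes, up, at adjusted p of 0.635 or more with an estimated correlation. Calcium handling genes, which include the atrial marker Sln, scored highest in the 4 libraries with atrial markers, 1 TG female and 1 TG male among them, and were also lower without these (adjusted p = 0.0019). The WT and TG comparisons share no libraries. Of their calls, 3 higher in females were shared (Armcx4, Col14a1 and Xist; 0.0032 for independent lists) and 12 lower (0.014), among them C7, Hsd11b1, Lvrn and Penk.

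**Figure D3:**
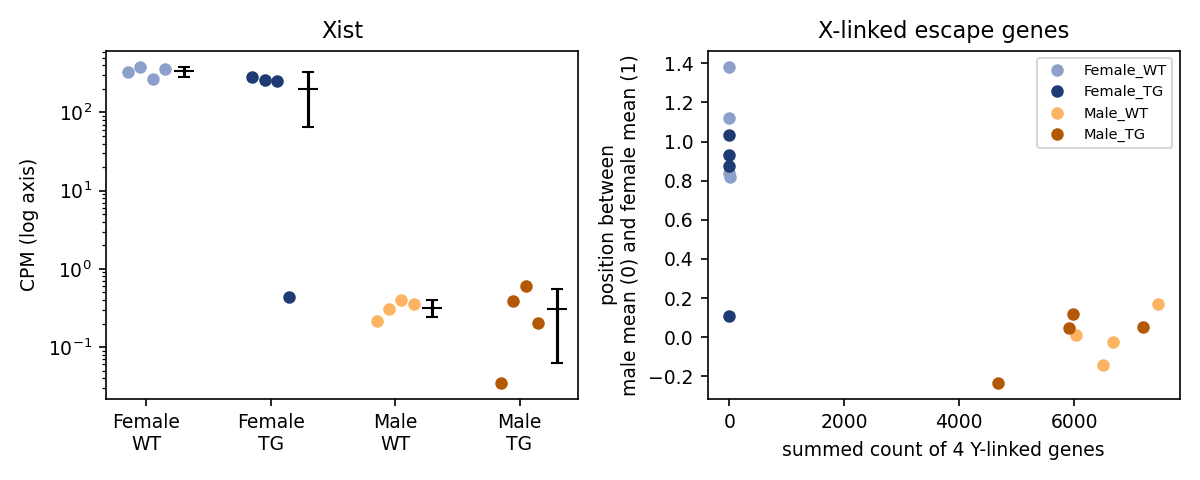
Left, Xist in CPM (log axis) by group, with points for hearts and mean ± SD (n = 4) beside them. Right, the mean position of the X-linked Kdm6a, Kdm5c, Eif2s3x and Ddx3x between the male mean (0) and the mean of females other than TG female replicate 4 (1), against the summed count of Ddx3y, Uty, Kdm5d and Eif2s3y; TG female replicate 4 lies at 0 counts and 0.11.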

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

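The tests of the library without Xist, of the chromosome 2 position and series, and of the atrial markers were chosen after the values were seen; the search for shared sequence and the splits of the samples were set before their results. Of 168 sets of 4 values examined, 19 held a library far from its group, where chance gives about 8.4, 1 in 20. That rate assumes independent, normally distributed values. The sets share libraries, so the 2 numbers are no test of an excess. Kdm5d, Ddx3y and Eif2s3y in WT females are among the 19 through 3, 4 and 12 counts in replicate 4, against 0 in the others.

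TG female replicate 4 had 0.441 CPM of Xist, against 248 to 284 in the other TG females, and 16.9 CPM of Kdm6a, against 28.0 or more. A mislabelled male is argued against by a summed count of 0 over Ddx3y, Uty, Kdm5d and Eif2s3y, where the lowest male library had 4668. Loss of Xist RNA alone is argued against by the X-linked genes that escape silencing, whose mean position was 0.107 on a scale from males (0) to other females (1), below the lowest other female at 0.819. A single X chromosome may account for both, since the highest male library lay at 0.168 on that scale. Without this library 1 gene was called for genotype in females and 21 for sex in TG.

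Myl7, Sln and Myl4, markers of atrial muscle, were highest in female WT replicates 1 and 2, TG female replicate 1 and male TG replicate 4, where Myl7 reached 9.60 to 35.3 CPM. Atrial tissue in these samples could account for this and stays open: of 11 other atrial genes tested, 3 (Dkk3, Mybphl and Cpne5) had exactly these 4 libraries highest, too many for none of them to follow Myl7 and too few for most of them to. Natriuretic peptide induction is argued against, as 2 of the 4 were among the 4 highest for Nppa, and 2 for Nppb.

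Other libraries far from their group are given as values. Female WT replicate 4 had 0.0902 CPM of Kdm5d, 0.120 of Ddx3y and 0.361 of Eif2s3y against 0 in the other WT females, with 73 of Nnt and 40.2 of Rnase4. Male WT replicate 1 had 2.11 CPM of Kcnh7, 70.5 of Eif2s3y and a mitochondrial share of 29.8%. Male TG replicate 4 had 84.9 CPM of Smoc2, 13.3 of Kdm6a and 0.913 of Lvrn. Male TG replicate 1 had 33.4 CPM of Fgl2 and 0.0475% of counts on haemoglobin genes, and male TG replicate 3 had 8.67 of Armcx4. TG female replicate 3 had 84.7 CPM of Smoc2, TG female replicate 4 33.5 of Fgl2, and TG female replicate 1 a total of 41.7 M counts.

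By the test of the difference, genotype effects differed between the sexes for 6 lists at camera's preset correlation: mitochondrially encoded mRNAs (adjusted p = 3.27e-05), interferon response (0.0120), fatty acid oxidation, PPAR targets and conduction system markers (0.0137 each) and fetal and hypertrophy genes (0.0329). With an estimated correlation the adjusted p of each was 0.82. Among 100 splits of the samples within each sex, 87 called as many lists (6, highest other 22), so chance is not excluded for them.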

How the results depend on the processing

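The fits without the 4 libraries with atrial markers, with the mitochondrial share, within the earlier and within the later series, and the lists without Abcc9 were chosen after seeing the data. Abcc9 kept its direction and call under all 27 alternatives that hold it (log2 fold change 3.79 to 3.90; 3.80 to 3.89 leaving out 1 library). Of named genes, 2027 gene and setting pairs kept their side of the threshold, 100 lost it, 22 gained it and 0 reversed; of called lists 1693 kept it, 429 lost it and 36 reversed. The cause was not tested unless stated.

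Counts of genes, in the order genotype across both sexes (3), in females (1), in males (1), interaction (0), sex in WT (27) and sex in TG (18), moved by over 1.5 times as follows. DESeq2 called 9, 9 and 2 for genotype, and 69 and 84 for sex. Limma-voom called 2 in females, 2 in males, 65 and 77. No filter gave 6 across both sexes. A fold of 2 left 1 across both sexes and 14 in WT, and an FDR of 0.10 gave 5 across both sexes and 28 in TG. The 8 female libraries alone gave 10. Leaving out Abcc9 and Myh6 gave 0 in females and 0 in males, as the gene called was removed. Without the 4 libraries with atrial markers there were 8 in females and 1 for the interaction, in a fit that cannot tell genotype from series among females. The mitochondrial share as a term gave 2 in males, 758 in WT and 103 in TG. The earlier series alone, with fewer samples, gave 6 and 11 for sex; the later series gave 3 in females, of which 1 is Xist, 1 for the interaction, Xist, and 9 and 7 for sex; its only TG female is replicate 4, which lacks Xist. Leaving out 1 library gave 3 to 4, 1 to 2, 1 to 2, 0, 19 to 44 and 14 to 35.

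Counts of lists were 12, 8, 19, 6, 10 and 13 in the same order. An estimated correlation gave 1, 1, 1, 0, 2 and 1, and fry 1, 1, 1, 0, 2 and 3. The later series gave 19, 20, 10 and 18 for genotype and interaction, the earlier series gave 11 in males, the series term 15 in females, limma-voom 9 in males and 3 for the interaction, the mitochondrial term 20 for the interaction, the libraries without atrial markers 10 in males and 7 in TG, the stricter filter 8 in TG, and DESeq2 and an FDR of 0.10 each 17 in WT. Leaving out 1 library gave 7 to 15, 8 to 13, 9 to 20, 1 to 11, 10 to 16 and 8 to 14.

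The correlation of genotype effects between the sexes was 0.055, -0.18 within the later series, and -0.20 to 0.017 leaving out 1 library. Fewer samples let in more low-count genes (15198 to 15272); over the genes of the full fit the range was -0.11 to 0.13, so its sign is not settled.

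Lists that reversed did so at these adjusted p. Those within a series rest on groups of 1 heart (WT female and TG male in the earlier series, TG female and WT male in the later), so they do not show that a direction turned. In the earlier series: extracellular matrix across both sexes 0.377 and in males 0.616, and in males PPAR targets 7.64e-06, circadian clock 0.943, interferon 0.0121, ribosomal proteins 0.555 and conduction system 0.616; for the interaction fatty acid oxidation 4.89e-04, PPAR targets 2.42e-05 and interferon 0.900; MHC for sex in WT 0.147 and erythroid markers in TG 0.229. In the later series: MHC across both sexes 0.625 and in females 0.0867; in males Complex I 0.905, inflammation 0.971, cell cycle 0.585, ribosomal proteins 0.0915 and skeletal muscle 0.971; in TG fatty acid oxidation 0.983, TCA cycle 0.349, ketone use 0.981 and mesothelial markers 0.880. Without the libraries with atrial markers: ribosomal proteins across both sexes 0.977 and in females 0.724, interferon in males 0.704. With Abcc9 out of the lists, KATP in males 0.997 and smooth muscle 0.441; with Abcc9 and Myh6 out, smooth muscle 0.410; by limma-voom 0.965. With the series term, ribosomal proteins in males 0.568 and PPAR targets for the interaction 0.490. With the mitochondrial term in TG, calcium handling 0.360 and extracellular matrix 0.704. Without male TG replicate 4, interferon in males 0.751 (2.04e-04 to 0.751 leaving out each library); without TG female replicate 1, mesothelial markers in TG 0.920 (3.81e-04 to 0.920). Depth limits genes of low count most: 98.1% of genes with a mean log2 CPM of at least 3 had an interval within a fold of 1.5 across both sexes, against 83.9% of all. No paired analysis was possible because the labels pair no hearts.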

Other observations

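The sequence search and the splits were set before their results; the tests of position and of the series and the count of splits without Abcc9 were chosen after the genes were seen. Of the 50 genes with the smallest genotype p across both sexes, Abcc9 left out, 7 lay in one window of 5 Mb on chromosome 2 from 62595798 (Ifih1, Gca, Kcnh7, Fign, Grb14, Cobll1 and Scn3a), and 0 of 10000 shuffles of gene positions gave as many (highest 6). Among 100 splits of the samples, which are a sample of the possible ones, 2 gave as many, the real one included (highest other 8). Another split thus put more genes in one window, so neighbouring genes can rank together under other labels. The shuffles of gene positions do not allow for that. Chance is made less likely but is not excluded. Reads shared with the overexpressed transcript are argued against for Fign, whose transcripts share 6 of 9982 words of 31 bases with Abcc9 or Myh6 transcripts; Kcnh7 shares 18 of 15144 and Gca and Ifih1 1 each, and these 3 were lower in TG, where added reads would raise them. The effect of the earlier against the later series was estimated at -0.12 to 0.18 in the 7 genes. For 7 of the 7 its 95% interval left out the size that would give the female or the male genotype effect. With the series as a term Fign kept 0.88 and Kcnh7 -0.94 (adjusted p = 0.0073 and 0.014). This test cannot decide on the series as a cause. The genes were picked across both sexes, where the pooled series are balanced, so a pooled effect would cancel whatever its size. Differences among the series pooled together are not covered by the term and stay open. DNA linked to one locus, such as an inserted transgene or flanking DNA of another origin, may account for the 7 genes; the insertion site was not mapped, and Gca and Kcnh7 overlap at their ends on opposite strands.

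For the counts of genes, other splits of the same hearts were fitted. Chance is made less likely for sex in WT (1 of 35 splits as large, 27 genes, highest other 2) and for sex in TG (1 of 35, 18 genes, highest other 1). The 1 is the real split, and 35 splits allow no smaller share, so they do not exclude chance. The series is partly mixed with sex, which the splits do not separate. The labels set the sex-linked calls, but the autosomal calls alone, 18 in WT and 11 in TG, exceeded the highest other split. For genotype across both sexes 2 of 100 splits called as many (3 genes, highest other 5), but the design sets 1 of these genes, Abcc9. Without Abcc9, 4 of 100 splits called as many (2 genes, highest other 5), a share just under 0.05. The 100 are a sample of the possible splits, so that share does not exclude chance for these 2 genes. Nor is chance excluded for the number of genes in females (3 of 35, 1 gene, highest other 40) or males (4 of 35, 1 gene, highest other 1606), a count that leaves out the size of the Abcc9 change. For the interaction, with 0 genes, every split gives as many (100 of 100, highest other 1072), so the splits say nothing about chance there. The male split with 1606 genes put libraries with 25.1% to 26.5% of counts on mitochondrially encoded mRNAs against those with 27.5% to 29.8%. A male split that followed the sample number series, earlier against later, called 142. Both kept 3 of 4 hearts of each genotype together, so they are not clear of genotype. Another male split, with 2 WT and 2 TG hearts on each side, called 98, which points to structure among the male hearts apart from genotype. It did not wholly separate the series or the mitochondrial shares, but it leaned with both. Its sides held 3 of 4 hearts of the later and 3 of 4 of the earlier series. Their mitochondrial shares were 25.1% to 27.5% and 26.0% to 29.8%. Male WT replicate 1 and male TG replicates 1 and 3, with the highest male shares, were on the same side. The split is therefore not clear of series or share. The female split that followed the series called 0, as did the female split with these shares apart. With a term for the series 1 gene, Abcc9, was called in males. For the lists chance is not excluded in any comparison: 48 of 100 splits for genotype across both sexes (12 lists, highest other 23), 30 of 35 in females (8, highest other 24), 4 of 35 in males (19, highest other 19), 24 of 35 for sex in WT (10, highest other 19) and 24 of 35 for sex in TG (13, highest other 21). Nor is it for the correlation between the sexes (29 of 100, 0.055, highest other 0.28).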
